A study of Mus musculus with 5 samples.

How the data were processed

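Gene expression was measured by RNA sequencing in NP-binding donor light zone B cells sorted from mouse spleen, with 3 libraries labelled Csk(+/+) and 2 labelled Csk(f/f), which the design text calls biological replicates. Per the labels, RNA was taken in TRIzol from the sorted cells and made into libraries with the NEBNext Ultra RNA kit. The deposited values were FPKM per gene, made by the authors with TopHat2 2.0.8 and Cufflinks 2.1.1 on the mm9 genome, with 1 column per library. The annotation, and whether the libraries were scaled against each other, are not stated in the sources used here. All 5 columns were mapped to a library by their labels. The table held 23234 genes, and 1 further line that repeated a header was left out. Counts, reads and exon-level values were not analysed here.

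The main comparison was Csk(f/f)-labelled minus Csk(+/+) libraries. Genes with an FPKM of at least 1 in at least 2 of the 5 libraries (10242 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended prior and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. Log2 fold changes are given with their standard error, and group values are mean FPKM ± SD over 3 and 2 libraries, written in the order Csk(+/+), Csk(f/f)-labelled. The Csk transcript was also tested by an exact permutation of the 5 FPKM values over their 10 splits. The replicate numbers were not taken as a pairing.

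Before the data were examined, the alternatives of the main analysis, 35 gene lists, a panel of genes and the rule for named genes were written. The rule named 3 sets of genes. The first was the panel. The second held, among genes with a mean FPKM of at least 5 in a group whose libraries did not overlap between groups, the 12 past the threshold with the largest and the 12 with the smallest log2 fold change, leaving out receptor gene segments, predicted genes, small RNAs and mitochondrial transcripts. Where fewer passed, places were filled by unadjusted p among such genes with a log2 fold change of at least 0.58 in size. The third held from each list up to 4 members past the threshold, or up to 2 with the smallest p where none passed. The panel held Csk, Nr4a1, Egr1, Cd69, Myc, Irf4, Cybb, Ncf1, Hmox1, Bcl2l11, Cxcr4, Cd83, Cd86, Bcl6 and Prdm1. A further panel gene and 2 genes named from lists are not reported here. The lists were BCR-induced, proximal BCR, Src family, inhibitory BCR, NADPH oxidase, antioxidant, BCL-2 family, p53 target, NF-kB target, light zone, dark zone, germinal centre identity, plasma cell, memory B, antigen presentation, MYC target, G1/S, G2/M, glycolysis, respiratory chain, adhesion and cytoskeleton, interferon and endoplasmic reticulum stress genes. Quality lists covered heat shock, mitochondrially encoded and ribosomal protein genes, and marker lists covered naive B, T, natural killer, dendritic, erythroid and stromal cells, macrophages, neutrophils and platelets. The 28 lists with at least 5 tested members were tested against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, adjusted over the 28 lists. With an estimated correlation camera takes its p from the residual degrees of freedom, which are few with 5 libraries. A call lost there therefore does not show that a list was unchanged.

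Transcript GC content, length, chromosome and gene order came from the GRCm38 annotation by gene name, taking the longest GENCODE transcript. Since the authors mapped to mm9, no coordinates were used. Of the tested genes, 10118 (98.8%) had a GC value and 10158 a chromosome. The GC correction, chosen after seeing the data, subtracted from each library the lowess trend (span 0.3) of its deviation from the gene mean against GC content. Alternatives tried were a pseudocount of 0.1 or 5, no filter, a filter at 5 FPKM, median-ratio rescaling, quantile normalization, robust empirical Bayes, no trend, array weights, the replicate number as a block and each library left out. Corrections for GC content and for transcript length were added, alone and in combination, with a fit without genes under 200 nt.

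Depth was estimated from the steps between the lowest FPKM values of genes with a transcript of at least 1500 nt, which put the relative depths at 1, 1.23, 0.749, 1.50 and 0.606. The pipeline was tested on simulated data with 10242 genes and 3 and 2 libraries, where it recovered 83.6% of genes changed 2 times, 100% of those changed 4 times and 95.5% of those changed 8 times, with 21 false calls. With a GC trend added it recovered 71.6%, 98.5% and 95.5% with 79 false calls, and after the GC correction 83.6%, 100% and 95.3% with 19 false calls. Only 67, 67 and 66 genes were changed (67, 66 and 64 in the corrected fit). The false calls thus exceeded the share that an adjusted p under 0.05 allows in all these fits. The excess was largest with a GC trend and no correction, which is the form of the main comparison. The simulated noise was independent between genes, no library was set apart, and changes were placed only in abundant genes. The shares recovered therefore do not give the power for the real libraries. There Abhd2, higher 2.9 times (limma adjusted p = 0.074), and Uap1l1, higher 2.4 times (0.0718), did not pass. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.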

Results

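RNA sequencing measured gene expression in germinal centre light zone B cells from mouse spleen. Light zone cells are the germinal centre B cells that take up antigen and meet T cell help. The cells came from donor B cells carrying the B1-8hi knock-in, an immunoglobulin heavy chain with affinity for the hapten NP, together with a tamoxifen-activated Cre (ERT2cre). Donor cells were either wild type or floxed at Csk, the kinase that phosphorylates the inhibitory tail tyrosine of Src family kinases. They were transferred into C57BL/6J mice, which were immunized with NP-CGG in alum on day 0, given tamoxifen on days 8 and 9, and used for sorting of NP-binding donor cells on day 11. There were 3 libraries labelled Csk(+/+) and 2 labelled Csk(f/f), and both groups received tamoxifen. The series title places the work in B cell receptor (BCR) signalling, reactive oxygen species and germinal centre selection, so the comparison asks how light zone B cells differ in expression once Csk has been deleted.

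The deposited table held FPKM values for 23234 genes. Genes above 0 numbered 14981, 14703 and 13291 in Csk(+/+) replicates 1, 2 and 3, and 14089 and 13422 in Csk(f/f) replicates 1 and 2. The steps between the lowest values put the depth at about 15.7, 19.4 and 11.9 M fragments for the Csk(+/+) libraries and 23.8 and 9.45 M for the Csk(f/f) libraries. Of all genes, 10242 reached an FPKM of 1 in at least 2 libraries and were tested.

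Csk transcript was not lower in the libraries labelled Csk(f/f). Its FPKM was 378, 436 and 415 in the Csk(+/+) libraries (410 ± 29.3, SD, n = 3) and 453 and 476 in the libraries labelled Csk(f/f) (464 ± 15.9, SD, n = 2). On the log2(FPKM + 1) scale the difference was 0.18 (95% CI -0.14 to 0.50, a fold of 1.14 with limits of 0.910 and 1.42), with a limma adjusted p of 0.439. A two-sided exact permutation test of the 5 values gave p = 0.2, where the smallest p these 10 splits allow is 0.1. The labels do not say which exons are floxed, and a gene-level FPKM includes exons outside a deleted part, so the values leave the genotype of these libraries unchecked. The groups are therefore named by their labels throughout. After a correction for transcript GC content the sign of the Csk difference turned (log2 difference -0.14, adjusted p = 0.818).

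A total of 8 genes passed the adjusted threshold, 4 higher and 4 lower in the libraries labelled Csk(f/f). Gdpd3, which encodes a lysophospholipase D, rose from 0.745 ± 0.121 FPKM (SD, n = 3) to 42.8 ± 2.77 (SD, n = 2), a log2 fold change of 4.65 ± 0.18 (SE). Inppl1, which encodes the inositol phosphatase SHIP2, rose from 3.88 ± 0.763 to 16.5 ± 0.756 FPKM (log2 fold change 1.86 ± 0.20). Trim12a, a member of the TRIM family, fell from 19.4 ± 1.45 to 0.737 ± 0.531 FPKM (log2 fold change -3.59 ± 0.23). Their limma adjusted p-values were 4.6e-05, 0.0333 and 0.00107. The other 5 genes lay outside the rule for named genes and were chosen after their values were seen. Gprc5b, an orphan G protein-coupled receptor gene, was listed at 0, 0.0327 and 0 FPKM in the Csk(+/+) libraries and at 2.01 and 1.90 in those labelled Csk(f/f) (log2 fold change 1.55, limma adjusted p = 0.038). Nucb2, which encodes the precursor of nesfatin-1, fell from 4.98 ± 1.14 to 0.252 ± 0.161 FPKM (log2 fold change -2.24, limma adjusted p = 0.023). The GC correction ended the calls of Gprc5b (log2 fold change 1.55 ± 0.17, SE, before and 1.38 ± 0.17 after, limma adjusted p = 0.0713) and Nucb2 (-2.24 ± 0.23 before and -1.84 ± 0.21 after, 0.0586), with most of the fold kept. Without a filter those of Inppl1 (0.272), Nucb2 (0.272) and Trim12a (0.0678) were lost at the same folds over more genes. Inppl1 and Nucb2 also lost theirs with any 1 library left out except Csk(+/+) replicate 3, at log2 fold changes of 1.81 to 1.95 and -2.38 to -2.11, and Gprc5b lost its call without Csk(+/+) replicate 1 or replicate 2 (1.54 and 1.56).

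The remaining 3 of the 8 were small RNAs with a longest annotated transcript under 200 nt, a length at which FPKM rests on very few usable fragment positions. Snord58b was listed at 0 in all 3 Csk(+/+) libraries and at 232 and 287 FPKM in the libraries labelled Csk(f/f). Mir1982 was listed at 166, 130 and 214 FPKM in the Csk(+/+) libraries and Mir680-1 at 35.5, 28.4 and 23.4 FPKM, and both were listed at 0 in the libraries labelled Csk(f/f). An exact 0 in such a table can be a failed estimate, so no fold is given for these 3. All 5 longer genes that passed, Gdpd3, Inppl1, Gprc5b, Nucb2 and Trim12a, lie on chromosome 7 of the GRCm38 annotation.

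**Figure D1:**
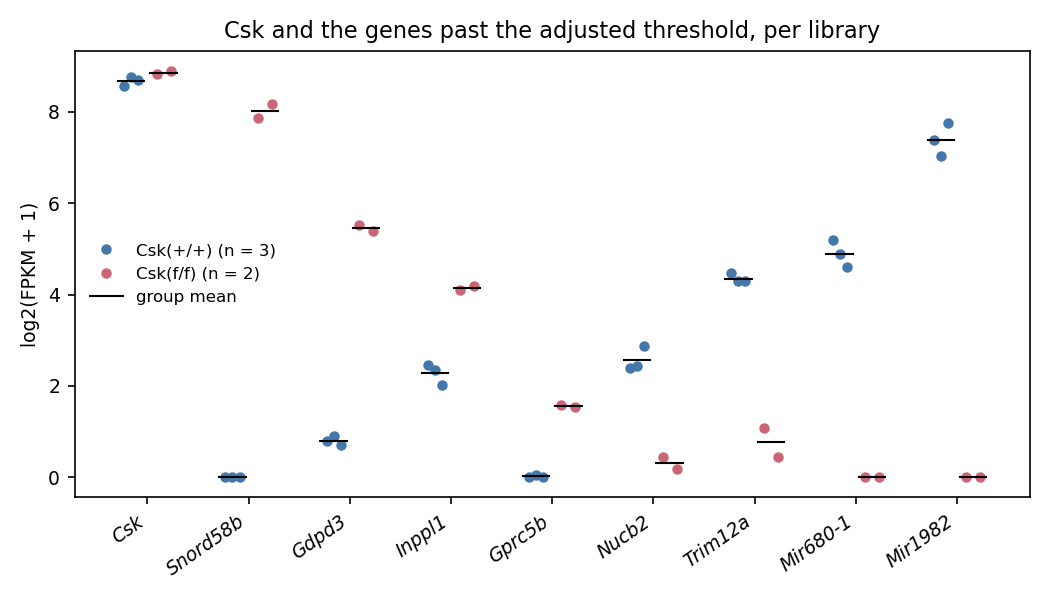
FPKM on a log2(FPKM + 1) axis for Csk and the 8 genes past the adjusted threshold, with 1 point per library (3 labelled Csk(+/+), 2 labelled Csk(f/f)) and a bar at each group mean. Csk lay between 378 and 476 FPKM in all 5 libraries, whereas Gdpd3 was 0.745 FPKM on average in one group and 42.8 in the other.

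Without Csk(+/+) replicate 3, which received the lowest library weight (0.259, the others 1.35 or more), 128 genes were higher and 283 lower, and with the GC correction as well 16 were higher and 24 lower. Genes under 200 nt made up 23 of the 411 and, with the GC correction, 13 of the 40. Several of them, such as Snora5c and Snord87, were listed at 0 in both Csk(f/f)-labelled libraries, which can be a failed estimate. Without either library labelled Csk(f/f), no gene passed as higher by limma, where 1332 genes without replicate 1 and 526 without replicate 2 had an unadjusted p under 0.05 in either direction. Gdpd3, Gprc5b and Snord58b are above 1 FPKM only in those 2 libraries and so fell outside the filter there.

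The genes next in rank under the rule did not pass the threshold. Their groups of libraries do not overlap because the rule asked for it. Several with higher values encode lysosomal proteins. The FPKM of Gaa, the lysosomal acid alpha-glucosidase, was 10.2 ± 1.48 (SD, n = 3) in Csk(+/+) and 23.7 ± 2.01 (SD, n = 2) in Csk(f/f)-labelled libraries. Psap, the precursor of the saposins, had 132 ± 16.8 and 239 ± 6.03 FPKM, and Dnase2a, the acid DNase of lysosomes, had 14.7 ± 1.34 and 28.5 ± 0.117. Each of these 3 genes had a limma adjusted p of 0.128. Uap1l1 (40.3 and 97.0 FPKM), Abhd2 (14.6 and 42.4), Bri3 (24.3 and 48.8), Vat1 (5.09 and 12.5), Mreg (5.77 and 13.3), the mitochondrial kinase gene Pink1 (15.4 and 29.6) and Renbp (7.25 and 17.4) also had higher means in the Csk(f/f)-labelled libraries, with adjusted p-values from 0.0718 for Uap1l1 to 0.128 for Renbp.

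Among genes with lower values that did not pass, Rgs10, a regulator of G protein signalling, had 46.1 ± 5.60 FPKM in Csk(+/+) and 24.0 ± 0.297 in the Csk(f/f)-labelled libraries. Hmgb2, a chromatin protein abundant in cycling cells, had 253 ± 40.3 and 125 ± 6.51 FPKM. The co-chaperone gene Dnaja1 had 29.5 and 14.4, Cetn3, which encodes a centrin, 40.9 and 16.7, Mzt1, a component of the gamma-tubulin ring complex, 14.8 and 6.50, and the heterochromatin protein gene Cbx3 111 and 51.5. The adaptor gene Nck1 (9.88 and 4.39 FPKM), the small GTPase gene Rap1a (115 and 51.8), Hrsp12 (11.2 and 4.04), Oxr1 (7.85 and 3.01) and Trim34a (6.42 and 1.23) completed the list, all with a limma adjusted p of 0.128.

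Fold changes followed the GC content of the transcript. Across 10118 genes with a GC value, the log2 fold change correlated with GC content with a Spearman rho of 0.71, across genes that are not independent replicates. The median log2 fold change was -0.47 in the bin of genes with the lowest GC content and 0.32 in the bin with the highest. Both Csk(f/f)-labelled libraries deviated upward with GC content (rho 0.54 and 0.66), and the Csk(+/+) libraries deviated downward (rho -0.56, -0.21 and -0.41). At an unadjusted p under 0.05 by limma there were 2221 genes, 827 higher and 1394 lower, where 512 of 10242 would be expected by chance. After subtracting the GC trend from each library there were 1008 of 10118. Quantile normalization gave 1130 higher and 1188 lower at that unadjusted p. FPKM values of single genes are given as deposited, so part of a difference can follow this trend. The log2 fold change of Igj moved from -0.64 to -0.13 with the GC correction, and that of Ccng1 from -0.65 to -0.21. Ndufa5 kept its own (-0.60 before and -0.63 after).

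**Figure D2:**
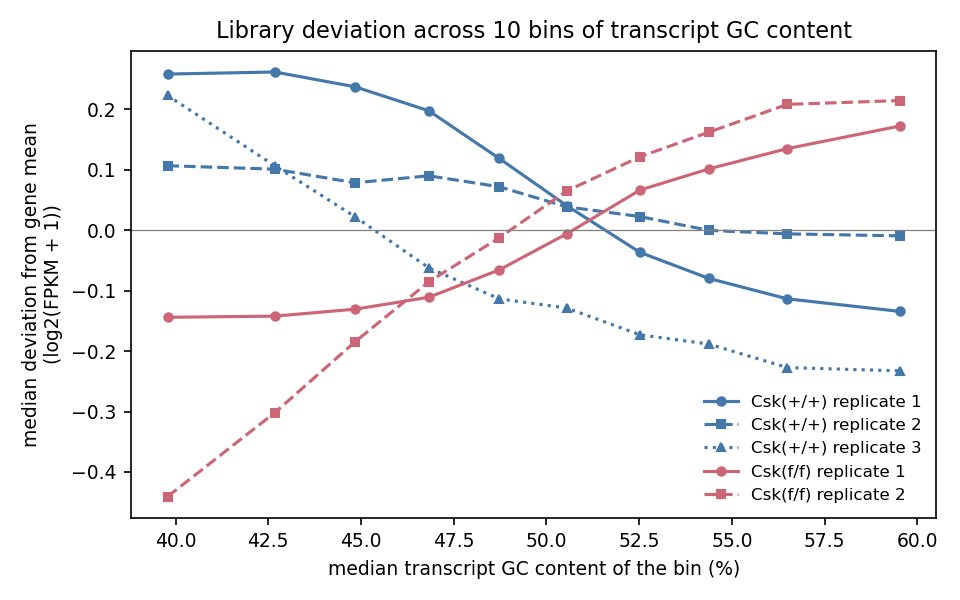
Median deviation of each library from the gene mean, on the log2(FPKM + 1) scale, for 10 bins of genes ordered by transcript GC content in percent, with 1 line per library. The 2 libraries labelled Csk(f/f) rise from left to right, and the 3 labelled Csk(+/+) descend.

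For BCR signalling, the list of genes induced by BCR ligation ranked higher than other genes in the libraries labelled Csk(f/f). Its 23 tested members had a median log2 fold change of 0.21, with 15 positive and a camera adjusted p of 0.046. With an estimated correlation the call was lost (adjusted p = 0.917). After the GC correction it was lost as well, with a median of 0.13 and 15 members still positive (adjusted p = 0.335). With the correction and a library left out it passed only without Csk(+/+) replicate 1 (median 0.24, adjusted p = 0.0086, and adjusted p = 0.876 with an estimated correlation), and not without Csk(+/+) replicate 2 (median 0.24, 0.0948), Csk(f/f) replicate 1 (0.18, 0.322) or Csk(f/f) replicate 2 (0.12, 0.349). As deposited it was lost without Csk(f/f) replicate 1 (median 0.32, adjusted p = 0.0761) and Csk(f/f) replicate 2 (0.24, 0.0676). Bhlhe40, a transcription factor gene, had 3.17 ± 1.42 FPKM (SD, n = 3) in Csk(+/+) and 11.9 ± 1.19 (SD, n = 2) in the Csk(f/f)-labelled libraries, and Nfkbid had 18.4 ± 3.70 and 33.5 ± 0.354. Adjusted over the list alone 2 members were higher and 0 lower (2 and 1 after the GC correction), and by limma over all genes tested 0 passed, with 4 higher at an unadjusted p under 0.05. The classical reporter of antigen receptor signalling, Nr4a1, had 3.60, 4.03 and 1.26 FPKM in the Csk(+/+) libraries and 4.00 and 3.87 in those labelled Csk(f/f) (adjusted p = 0.502). Egr1 (26.0 ± 6.43 and 20.9 ± 2.57 FPKM), Cd69 (10.6 ± 2.91 and 6.96 ± 3.25), Myc (40.3 ± 7.51 and 39.0 ± 0.283) and Irf4 (10.8 ± 3.15 and 15.2 ± 2.91) did not pass either, with limma adjusted p-values of 0.467, 0.310, 0.922 and 0.303. Csk(+/+) replicate 3 stood apart for this list, with a median deviation of -0.51 against 0.10 to 0.20 in the other 4 libraries. Without that library the list median was 0.04 (camera adjusted p = 0.328), and with the GC correction it was -0.07.

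The NF-kB target list behaved alike, with 27 members, a median of 0.27 and a camera adjusted p of 0.047. That call was lost with an estimated correlation (adjusted p = 0.917), after the GC correction (median 0.09, adjusted p = 0.254) and without Csk(+/+) replicate 3 (median 0.13, adjusted p = 0.288). It was lost too without Csk(f/f) replicate 1 (median 0.29, adjusted p = 0.101) and without Csk(f/f) replicate 2 (0.24, 0.0961). Nfkbie, an inhibitor of NF-kB, had 67.6 and 107 FPKM, and Birc2 had 16.8 and 9.92. By limma over all genes 0 members passed, with 10 higher and 2 lower at an unadjusted p under 0.05 (2 and 1 after the GC correction), and adjusted over the list alone 0 passed.

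Lists of BCR pathway components did not pass by camera, which tests for a shift in one direction and can miss opposite changes. In the proximal list 1 member was higher and 5 lower at an unadjusted p under 0.05 by limma. The 29 tested proximal BCR signalling genes had a median log2 fold change of 0.08 (camera adjusted p = 0.917), the 6 Src family and related kinases 0.05 (adjusted p = 0.487), and the 26 inhibitory receptors, phosphatases and adaptors 0.07 (adjusted p = 0.785). Blk, a B cell Src family kinase, had 108 ± 11.6 FPKM (SD, n = 3) in Csk(+/+) and 176 ± 4.02 (SD, n = 2) in the Csk(f/f)-labelled libraries, with a limma adjusted p of 0.132 over all genes, and passed when adjusted over the Src family list alone, as 1 of 6. Fgr had 9.52 and 11.8 FPKM. Among the inhibitory genes, Rasa1 had 4.80 and 2.41 FPKM and Rasal3 52.1 and 74.0, and 0 passed adjusted over the list alone. In the proximal list 1 member was higher and 3 lower adjusted over the list alone (0 and 0 after the GC correction), Nck1 and Blk having the smallest p-values. By limma 0 members of any of the 28 lists passed over all genes.

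For reactive oxygen species, neither the NADPH oxidase list nor the antioxidant list passed with all 5 libraries. The 10 tested oxidase genes had a median log2 fold change of 0.22 (camera adjusted p = 0.205, and 0.501 after the GC correction). Cybb, the catalytic gp91phox subunit, had 69.3 ± 6.86 FPKM (SD, n = 3) in Csk(+/+) and 61.8 ± 14.6 (SD, n = 2) in the Csk(f/f)-labelled libraries (adjusted p = 0.557, with the sign turned to a log2 difference of 0.20 by the GC correction), and Ncf1, the p47phox subunit, 93.7 ± 11.4 and 111 ± 8.80 (adjusted p = 0.346). Adjusted over the list alone 2 oxidase genes were higher and 1 lower (1 and 1 after the GC correction), the lower gene being Rap1a. The 33 antioxidant genes had a median of 0.06 (camera adjusted p = 0.428) and 0 passed adjusted over the list alone, including Sesn3 (26.6 and 19.5 FPKM), Gsto1 (8.78 and 12.6) and Hmox1, the haem oxygenase induced by oxidative stress (1.95 ± 0.556 and 2.46 ± 0.822, SD, n = 3 and n = 2). With the GC correction and without Csk(+/+) replicate 3 the antioxidant list passed as higher (median 0.20, camera adjusted p = 0.0077, and adjusted p = 0.718 with an estimated correlation).

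For survival, the 17 BCL-2 family genes had a median log2 fold change of -0.02 (camera adjusted p = 0.873) and the 23 p53 targets -0.02 (adjusted p = 0.753). Bcl2l11, which encodes the pro-death protein BIM, had 8.83 ± 1.72 FPKM (SD, n = 3) in Csk(+/+) and 8.34 ± 2.05 (SD, n = 2) in the Csk(f/f)-labelled libraries, and its sign turned after the GC correction (log2 difference -0.07 before and 0.03 after). Bak1 had 76.0 and 100 FPKM, Bcl2a1b 134 and 105, Trp53inp1 11.1 and 6.24, and Ccng1 35.5 and 22.3. In both lists 0 genes passed by limma over all genes and 0 adjusted over the list alone, with 1 higher and 1 lower BCL-2 family gene and 3 lower p53 targets at an unadjusted p under 0.05.

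Genes of mitosis were the most uniform group. All 28 members of the G2/M list had lower means on the log2 scale in the Csk(f/f)-labelled libraries, with a median log2 fold change of -0.51 and a camera adjusted p of 7.4e-09. After the GC correction all 28 stayed negative (median -0.39, adjusted p = 7.1e-11). With an estimated correlation the call was lost (adjusted p = 0.637, and 0.847 after the GC correction). Kif23, a mitotic kinesin, had 20.1 ± 2.94 FPKM (SD, n = 3) in Csk(+/+) and 9.84 ± 2.49 (SD, n = 2) in the Csk(f/f)-labelled libraries, and Prc1, a cytokinesis regulator, had 20.6 ± 1.72 and 11.0 ± 1.37. Adjusted over the list alone 15 members were lower as deposited and 0 after the GC correction, and by limma over all genes 0 passed, with 20 lower at an unadjusted p under 0.05 (16 after the correction). Csk(+/+) replicate 3 stood apart here too, with a median deviation of 0.36 against 0.14 and 0.12 in the other Csk(+/+) libraries and -0.23 and -0.41 in those labelled Csk(f/f).

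The dark zone list, genes higher in dark zone than in light zone cells, shared 13 of its 20 genes with the G2/M list. Its 19 tested members had a median of -0.45 (camera adjusted p = 2.1e-05, and adjusted p = 0.637 with an estimated correlation), 9 being lower adjusted over the list alone (0 after the GC correction) and 0 by limma over all genes, where 13 were lower at an unadjusted p under 0.05. The median deviation of Csk(+/+) replicate 3 was 0.35, against 0.10 and 0.12 in the other Csk(+/+) libraries. Nusap1, a mitotic spindle gene, had 24.0 and 12.8 FPKM. After the GC correction the whole dark zone list still passed (median -0.41, camera adjusted p = 5.4e-05), though not with an estimated correlation (adjusted p = 0.917). The 6 tested dark zone genes outside the G2/M list had a median of -0.31 and, after the GC correction, -0.02. Cxcr4, the chemokine receptor of dark zone positioning, had 61.2 ± 2.49 FPKM (SD, n = 3) and 64.0 ± 1.69 (SD, n = 2), with a limma adjusted p of 0.762.

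The light zone list did not pass (28 members, median log2 fold change 0.21, camera adjusted p = 0.205). Cd83 had 390 ± 12.1 FPKM (SD, n = 3) in Csk(+/+) and 501 ± 19.9 (SD, n = 2) in the Csk(f/f)-labelled libraries, whereas Cd86 had 76.6 ± 3.66 and 60.2 ± 4.63, with limma adjusted p-values of 0.197 and 0.196, and the Cd86 difference was gone after the GC correction (log2 difference 0.00396). Il4i1 had 284 and 410 FPKM and Lmo2 88.5 and 64.6. Genes of G1/S and DNA replication had a median of -0.07 (27 members, adjusted p = 0.371), with Mcm4 at 78.1 and 45.7 FPKM and Pcna at 479 and 334. Germinal centre identity genes had a median of -0.11 (29 members, adjusted p = 0.877). Bcl6, the master transcription factor of germinal centre B cells, had 72.3 ± 11.1 and 57.4 ± 2.51 FPKM (adjusted p = 0.274), Fbxo5 17.0 and 8.08, and Mybl1 19.1 and 9.69. Plasma cell genes had a median of -0.06 (18 members, adjusted p = 0.917), with Igj, the J chain gene, at 134 and 85.3 FPKM and Ell2 at 12.8 and 6.85. Prdm1, the plasma cell regulator, was below the filter, at 0.458, 0.2 and 0 FPKM in the Csk(+/+) libraries and 0.125 and 0.136 in those labelled Csk(f/f). Adjusted over the list alone the light zone list had 0 passing members, G1/S 1 lower, germinal centre identity 1 higher and 5 lower, and plasma cell 2 lower, and after the GC correction the last 3 lists had 0 and the light zone list 1 lower.

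Naive and memory B cell genes ranked higher in the libraries labelled Csk(f/f). The 10 tested naive B cell markers had a median log2 fold change of 0.35 (camera adjusted p = 0.0079) and the 18 memory B cell genes 0.27 (adjusted p = 0.046), and after the GC correction the medians were 0.40 (adjusted p = 8.2e-06) and 0.18 (adjusted p = 0.0035). With an estimated correlation both calls were lost (adjusted p = 0.637 and adjusted p = 0.680). The lists share 6 genes, among them Ccr7, the chemokine receptor of T zone homing, and S1pr1, the receptor for exit from lymphoid tissue. Ccr7 had 0.277 ± 0.0884 FPKM (SD, n = 3) in Csk(+/+) and 1.96 ± 0.169 (SD, n = 2) in the Csk(f/f)-labelled libraries, and S1pr1 had 0.266 ± 0.0311 and 1.87 ± 0.535, with limma adjusted p-values of 0.128. Both genes reached 1 FPKM only in the 2 libraries labelled Csk(f/f), so the filter could admit them only as higher. With either of those libraries left out they fall outside the filter. With no filter both lists passed by camera (medians 0.22 and 0.15, adjusted p = 0.00997 and 0.0183), but not with an estimated correlation (0.699 and 0.762). At the 5 FPKM filter both camera calls were lost (0.30 and 0.27, adjusted p = 0.345 for each). Without the shared genes neither list ranked higher as deposited (medians 0.17 and 0.15, 0.406 and 0.395 by camera), whereas after the GC correction the naive part did (0.27, 0.0080 by camera, and 0.205 with an estimated correlation) and the memory part did not (0.13, 0.123 by camera). Adjusted over the list alone 4 naive markers were higher and 1 lower (5 and 0 after the GC correction), and 3 memory genes were higher (4 after it), with 0 passing by limma over all genes in either. The memory call was lost without Csk(+/+) replicate 3 (median 0.10, adjusted p = 0.109) but held there with the GC correction (median 0.18, adjusted p = 0.029, and adjusted p = 0.718 with an estimated correlation). It was lost without either library labelled Csk(f/f), with medians of 0.28 and 0.18 (adjusted p = 0.265 without replicate 1 and 0.203 without replicate 2), and with the GC correction as well (adjusted p = 0.181 and 0.146). The naive call was lost without Csk(f/f) replicate 1 (median 0.39, adjusted p = 0.16) and without Csk(f/f) replicate 2 (median 0.14, adjusted p = 0.202), and with the GC correction it held in both (adjusted p = 0.0046 and 0.045, and adjusted p = 0.959 and 0.886 with an estimated correlation).

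The antigen presentation list passed only after the GC correction (30 members, median 0.28 before and 0.14 after, camera adjusted p = 0.165 before and 0.0061 after, and adjusted p = 0.617 after it with an estimated correlation). Its members H2-DMb1 and H2-DMb2, which load peptide onto MHC class II, had 260 and 340 FPKM and 761 and 1055 FPKM, and 0 genes passed adjusted over the list alone. Heat shock genes did not pass as deposited and passed after the correction (11 members, median -0.55 before and -0.38 after, adjusted p = 0.074 before and 0.0061 after, and adjusted p = 0.405 after it with an estimated correlation). They also passed without it at a pseudocount of 5 (median -0.28, adjusted p = 0.035) and with quantile normalization (median -0.56, adjusted p = 0.025), and not there with an estimated correlation (adjusted p = 0.563 and 0.599). Hsph1 had 35.2 and 23.3 FPKM, and 2 heat shock genes were lower adjusted over the list alone (1 after the GC correction).

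The glycolysis list ranked higher (20 members, median log2 fold change 0.21, camera adjusted p = 0.047), and the call was lost with an estimated correlation (adjusted p = 0.637) and after the GC correction (median 0.01, adjusted p = 0.703). It was also lost, at medians of 0.17 to 0.24, without any one of Csk(+/+) replicate 1 (adjusted p = 0.123), Csk(+/+) replicate 2 (0.138), Csk(f/f) replicate 1 (0.101) and Csk(f/f) replicate 2 (0.0699), and it held without Csk(+/+) replicate 3 (median 0.24, adjusted p = 0.0067, and adjusted p = 0.757 with an estimated correlation). Pfkp, a phosphofructokinase, had 55.8 and 71.0 FPKM and the lactate transporter gene Slc16a1 19.6 and 14.0, and 0 passed adjusted over the list alone. Respiratory chain genes (44 members, median 0.03, adjusted p = 0.873) included Ndufa5 at 72.5 and 47.6 FPKM and Cox7b at 72.1 and 48.4, and passed as higher without Csk(+/+) replicate 3 (median 0.15, adjusted p = 0.0064, and 0.17, adjusted p = 0.00042, with the GC correction), though not with an estimated correlation (adjusted p = 0.757 and 0.718). MYC targets (35 members, median 0.02, adjusted p = 0.829) included Npm1 at 596 and 339 FPKM and Cad at 47.1 and 71.3, and adjusted over the list alone 3 were higher and 4 lower (0 and 0 after the GC correction). Adhesion and cytoskeleton genes (33 members, median -0.01, adjusted p = 0.739), with Itgb2 at 130 and 170 FPKM and Cdc42 at 242 and 183, did not pass. Nor did interferon genes (19 members, median 0.05, adjusted p = 0.428), with Irf7 at 15.2 and 20.9 FPKM and Parp14 at 8.04 and 5.31, or stress genes of the endoplasmic reticulum (23 members, median 0.13, adjusted p = 0.454), with Hspa5 at 210 and 148 FPKM and Hsp90b1 at 58.2 and 38.1. The median, the mean and the test differed in sign for 6 lists, the proximal BCR, inhibitory BCR, BCL-2 family, MYC target, respiratory chain and adhesion lists, none of which passed.

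**Figure D3:**
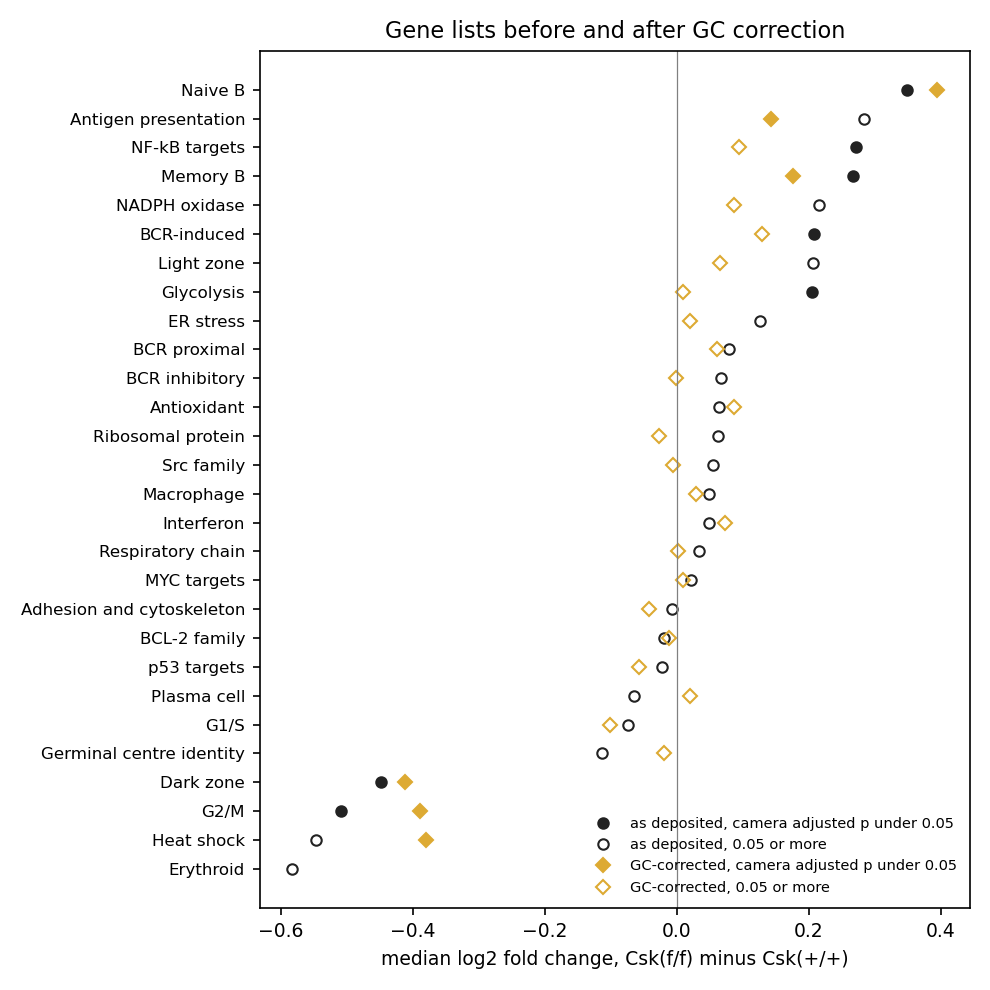
Median log2 fold change (Csk(f/f)-labelled minus Csk(+/+)) of the 28 tested gene lists, as deposited (circles) and after the GC correction (diamonds, not drawn for the erythroid list), filled where the camera adjusted p is under 0.05. The G2/M list lay at -0.51 and -0.39, and the glycolysis list moved from 0.21 to 0.01.

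Ribosomal protein genes did not pass (64 members, median log2 fold change 0.06, camera adjusted p = 0.537), with Rpl5 at 862 and 671 FPKM (a difference whose sign turned after the GC correction) and Rpl30 at 63.1 and 78.4. Without Csk(+/+) replicate 3 they passed as higher (median 0.25, adjusted p = 1.8e-06, and 0.20, adjusted p = 1.1e-05, with the GC correction), and with an estimated correlation they did not (adjusted p = 0.757, and 0.886 with the GC correction). Their share of all FPKM was 22.5%, 23.4% and 29.0% in the Csk(+/+) libraries and 26.2% and 24.5% in those labelled Csk(f/f), Csk(+/+) replicate 3 being the highest. Macrophage markers (5 tested, median 0.05, adjusted p = 0.536) were low, Lyz2 having 5.49 and 11.2 FPKM and Cd68 10.7 and 12. Erythroid markers (8 tested, median -0.58, adjusted p = 0.454) varied between libraries of one group. Hbb-b1, a haemoglobin chain gene, had 57.4, 217 and 133 FPKM in the Csk(+/+) libraries and 72.2 and 33.6 in those labelled Csk(f/f). The list passed as lower without Csk(+/+) replicate 1 (median -1.10, adjusted p = 0.035, and adjusted p = 0.978 with an estimated correlation). Only 6 of the 8 erythroid genes (75%, under the 80% asked of a list) had a GC value, so the GC check of that list is void. T cell, neutrophil, dendritic cell, natural killer cell, platelet and stromal markers had too few genes past the filter for a test (4, 1, 2, 2, 2 and 1). Their most abundant members were Cd2 (61.6 FPKM on average over all libraries), Cxcr2 (2.02), Bst2 (26.0), Tbx21 (3.91), Itgb3 (8.95) and Pecam1 (16.8). None of the 15 mitochondrially encoded genes sought was among the listed genes.

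On chromosome 7, the 5 longer genes that passed spanned positions 491 to 616 in the order of its 769 tested genes. Inppl1 came first, followed by Trim12a, Nucb2, Gprc5b and Gdpd3. Of the other 121 genes in that stretch with a GC value, 10 (8.26%) had an unadjusted p under 0.01 after the GC correction, against 222 of 9980 (2.22%) elsewhere. Trim34a, next to Trim12a in the order, was one of them, with a GC-corrected log2 fold change of -1.41. The median GC-corrected log2 fold change of the stretch was -0.06 (95% bootstrap interval -0.14 to 0.02).

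**Figure D4:**
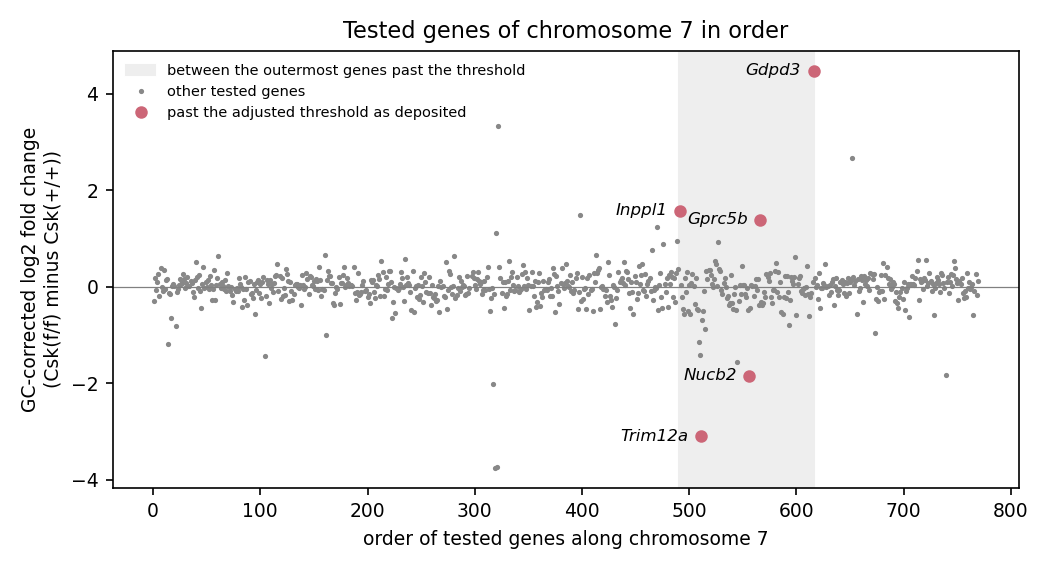
GC-corrected log2 fold change (Csk(f/f)-labelled minus Csk(+/+)) of tested genes on chromosome 7 with a GC value, in gene order, with the genes past the adjusted threshold as deposited named and the stretch between them shaded. The 5 named genes lie between positions 491 and 616, and they go in both directions.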

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

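The alternatives of the main analysis were fixed before the data were examined. The GC and length corrections, their combinations with the replicate block and with left-out libraries, the run without genes under 200 nt and the parts of overlapping lists were chosen after seeing the data. DESeq2 was not run, because FPKM values are not counts.

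Of the 8 genes past the threshold, Gdpd3 kept its call in 20 of 20 settings, Trim12a in 23 of 24, Inppl1 in 16 of 24, Nucb2 in 12 of 23 and Gprc5b in 11 of 19, all without a change of direction, and the 3 small RNAs kept theirs wherever they were tested. Without Csk(+/+) replicate 3 the genes past the threshold became 128 higher and 283 lower (GC-corrected 16 and 24), whereas leaving out any other library gave as few as 0 higher and 5 lower (GC-corrected 0 higher without Csk(f/f) replicate 1 and 0 without Csk(f/f) replicate 2). A left-out Csk(f/f) library leaves 1 in that group, so those fits assume that it varies as the Csk(+/+) libraries do, and Gdpd3, Gprc5b and Snord58b then fall outside the filter and only 1 gene past the threshold lies on chromosome 7. Genes under 200 nt made up 23 of the 411 calls without Csk(+/+) replicate 3, and 13 of 40 with the GC correction. Array weights gave 194 higher and 477 lower, no filter gave 2 lower, and the length correction gave 7 higher. The replicate block gave 110 higher and 382 lower, and with the GC correction 98 and 75. In that block Csk(+/+) replicate 3 shares its number with no other library and so drops out of the comparison. Deviations of libraries sharing a number correlated at -0.13 for number 1 and 0.11 for number 2. With 2 Csk(f/f) libraries their deviations mirror each other, so this check cannot exclude a shared batch or pairing. The labels give only a number, so nothing was paired. With 2 libraries in one group and 1 of 3 others apart from the rest, the counts past the threshold depend on which libraries are used.

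Lists passing as higher numbered 5. They became 2 with a pseudocount of 0.1, 0 with the stricter filter, where fewer genes were tested, 3 with quantile normalization, 3 with array weights, 3 with the GC correction, 1 with the length correction and 0 to 4 with a library left out. With the GC correction and a library left out, they were 4 without Csk(+/+) replicate 1, 3 without Csk(+/+) replicate 2, 6 without Csk(+/+) replicate 3 (6 also with the replicate block and the GC correction), 2 without Csk(f/f) replicate 1 and 1 without Csk(f/f) replicate 2, and lists passing as lower were 5, 5 and 4 without Csk(+/+) replicate 1, Csk(+/+) replicate 2 and Csk(f/f) replicate 1, counting in the first and last of these the erythroid list, whose GC check is void. With an estimated correlation and with fry, both fixed beforehand, 0 lists passed in either direction. The estimated correlation was applied to the other settings after seeing the data, and no list call made in any of them was kept with it. Its p rests on few residual degrees of freedom (1 in the replicate block fit), so a list could hardly pass. The glycolysis list lost its call there although its estimated correlation, -0.023, lay below the preset 0.01. The G2/M median stayed between -0.59 and -0.29 and the dark zone median between -0.52 and -0.30. The Csk difference turned to -0.14 with the GC correction, to -0.074 with the replicate block as well, and to -0.19, -0.16, -0.075, -0.13 and -0.15 with the GC correction and Csk(+/+) replicate 1, 2, 3 and Csk(f/f) replicate 1, 2 left out in turn.

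The following turned direction, and the cause was not tested. The BCR-induced list alone had passed as deposited, and in the alternative only the ribosomal protein list (GC-corrected, without Csk(+/+) replicate 1 or without replicate 2) and the MYC target list (GC-corrected, without Csk(+/+) replicate 2) passed. For lists the direction is that of the camera test and the value is the median log2 fold change. With the stricter filter: lists proximal BCR 0.085 and respiratory chain 0.034. With quantile normalization: lists proximal BCR 0.050, inhibitory BCR 0.063, MYC target -0.0023, respiratory chain -0.016, adhesion -0.060 and ribosomal protein 0.017, and gene Bcl2l11 0.0024. With array weights: lists proximal BCR -0.016 and inhibitory BCR -0.13. With the replicate block: lists proximal BCR -0.026 and inhibitory BCR -0.16. With the GC correction: lists proximal BCR 0.062, inhibitory BCR -0.0014, BCL-2 family -0.013, MYC target 0.0095, adhesion -0.042 and ribosomal protein -0.027, and genes Cybb 0.20, Bcl2l11 0.026, Cd86 0.0040 and Rpl5 0.014. With the length correction: lists BCL-2 family 0.00068, germinal centre identity -0.0079 and respiratory chain 0.012, and gene Bcl2l11 0.00068. With the replicate block and the GC correction together: lists BCR-induced -0.067, proximal BCR -0.032, inhibitory BCR -0.11, BCL-2 family 0.027, plasma cell 0.025 and adhesion -0.0023, and genes Nr4a1 -0.19, Cybb 0.26, Cd86 0.028, Bcl2a1b 0.063, Cdc42 0.067, Rpl5 0.14 and Cd68 -0.0070. GC-corrected and without Csk(+/+) replicate 1: lists proximal BCR 0.024, Src family -0.045, inhibitory BCR 0.015, MYC target -0.026, respiratory chain -0.11, adhesion -0.060 and ribosomal protein -0.16, and genes Cd69 0.16, Cybb 0.20, Bcl2l11 0.067 and Cd68 -0.063. GC-corrected and without Csk(+/+) replicate 2: lists BCL-2 family -0.031, MYC target -0.073, respiratory chain -0.092 and ribosomal protein -0.15, and genes Cd69 0.097, Cybb 0.15, Hmox1 -0.11 and Bcl2l11 0.076. GC-corrected and without Csk(+/+) replicate 3: lists BCR-induced -0.070, proximal BCR -0.031, inhibitory BCR -0.11, BCL-2 family 0.027, plasma cell 0.025 and adhesion -0.0028, and genes Nr4a1 -0.19, Cybb 0.26, Cd86 0.030, Bcl2a1b 0.066, Cdc42 0.070, Rpl5 0.15 and Cd68 -0.0089. GC-corrected and without Csk(f/f) replicate 1: lists MYC target -0.065, respiratory chain -0.094, endoplasmic reticulum stress -0.021 and ribosomal protein -0.17, and genes Cybb 0.049, Hmox1 -0.22, Bcl2l11 0.23, Slc16a1 0.060, Cdc42 0.022 and Rpl5 0.063. GC-corrected and without Csk(f/f) replicate 2: lists proximal BCR -0.010, inhibitory BCR -0.048, BCL-2 family -0.0079, plasma cell 0.066, MYC target 0.072 and adhesion -0.045, and genes Cd69 0.24, Cybb 0.36, Cd86 0.016, Bcl2a1b 0.0020 and Cd68 -0.071. With fry: lists proximal BCR 0.079, BCL-2 family -0.020 and respiratory chain 0.034. With a library left out, the ranges of those that turned were plasma cell list -0.17 to 0.029, respiratory chain list -0.047 to 0.15, ribosomal protein list -0.061 to 0.25, Myc -0.14 to 0.11, Bcl2l11 -0.30 to 0.15, BCL-2 family list -0.20 to 0.14, MYC target list -0.016 to 0.066, erythroid list -1.17 to 0.21, proximal BCR list -0.026 to 0.14, inhibitory BCR list -0.16 to 0.17, Hmox1 -0.015 to 0.47 and Cybb -0.42 to 0.062.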

Other observations

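Lysosomal genes had higher values in the libraries labelled Csk(f/f), although no member passed the adjusted threshold. Gaa, Psap and Dnase2a drew attention among the named genes, and a list of lysosomal genes whose values had not been seen was then written, with its prediction, before it was tested. Of its 47 genes 44 were tested, and 42 of these were positive after the GC correction, with a median log2 fold change of 0.33 (0.38 as deposited). After the GC correction 17 members had an unadjusted p under 0.05 as higher and 0 as lower by limma. The list ranked above other genes (4.3e-13 by camera in limma at the preset correlation, 0.029 with an estimated correlation and 0.052 with an estimated correlation as deposited). Lgmn, which encodes an asparaginyl endopeptidase of the antigen-processing pathway, had 151 ± 18.5 FPKM (SD, n = 3) in Csk(+/+) and 239 ± 23.3 (SD, n = 2) in the Csk(f/f)-labelled libraries. Lamp1, a lysosomal membrane glycoprotein gene, had 96.7 ± 4.32 and 143 ± 6.44, Grn, the progranulin gene, 21.3 ± 3.69 and 40.2 ± 3.22, and Atp6ap1, an accessory subunit gene of the proton pump, 41.1 ± 6.85 and 68.3 ± 5.41.

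The estimate depends on how far lysosomal genes vary together. With an estimated correlation, a library left out and the GC correction the list gave 0.017 to 0.118, with medians of 0.29 to 0.36. The data may reflect a coordinated difference of lysosomal genes between the 2 sets of libraries (unadjusted p of 4.3e-13 by camera, or 0.029 with an estimated correlation). Macrophage genes were uneven beside them, Lyz2 having 5.49 and 11.2 FPKM and Cd68 10.7 and 12, while naive B markers also ranked higher. These 5 libraries do not separate genotype from another property that the sets may share.

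For the 3 patterns weighed next, all tests were chosen after the result was seen, except those of a copy gain or loss and of an exchange of libraries, which were written before their values were examined.

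Fold changes followed transcript GC content, and so did differences between libraries with the same label. The 2 libraries labelled Csk(f/f) differed from each other along GC content with a rho of 0.32, and the Csk(+/+) pairs with 0.44, 0.01 and -0.22, so a bias of library preparation or sequencing may account for part of the trend. The trend that the GC correction removes was not the whole of the lower G2/M values, since all 28 members stayed negative after it (camera adjusted p = 7.1e-11). With an estimated correlation the list did not pass (adjusted p = 0.847), and a bias that the correction leaves in place is not excluded. Its corrected median deviations were 0.07, 0.06 and 0.38 in Csk(+/+) replicates 1, 2 and 3 and -0.13 and -0.31 in Csk(f/f) replicates 1 and 2, so Csk(+/+) replicate 3 added to the difference. For the BCR-induced genes the share of the GC trend stays open, since the call ended (camera adjusted p = 0.335) as the median moved from 0.21 (quartiles -0.05 and 0.49) to 0.13 (-0.14 and 0.26) with 15 of 23 members positive both times. Their higher rank rested on Csk(+/+) replicate 3, whose GC-corrected median deviation was -0.43 against 0.05 to 0.24 in the other libraries. Without that library the list median was 0.04, and -0.07 with the GC correction. Whether a shift toward cells outside division also contributes to the G2/M values was not tested.

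All 5 genes of at least 200 nt past the threshold lay on chromosome 7, where 769 of the 10158 tested genes with a chromosome lie, for an exact hypergeometric p of 2.5e-06. Since chromosome 7 was singled out after the genes were seen, the exact probability of all 5 on any 1 chromosome was computed as well, and at 1.5e-05 it argued against chance position. Settings with more calls put a smaller share there, with 35 of 411 without Csk(+/+) replicate 3, 53 of 671 with array weights and 34 of 492 with the replicate block. With the GC correction the share was 10 of 40 without Csk(+/+) replicate 3 and 24 of 173 with the replicate block. Other genes of the stretch between them also differed more often than genes elsewhere (odds ratio 3.96, one-sided Fisher exact p = 0.00046, 0.00092 adjusted for 2 regions), among them Trim34a, Trim34b, Dkk3, Tpp1 and Pgap2. The stretch was bounded by genes that passed in these same data, which that adjustment does not cover. Neighbouring genes need not be independent, and Tpp1 also belongs to the lysosomal list. The median GC-corrected log2 fold change of the stretch was -0.057, which argued against a gain or loss of a copy. A linked segment from another mouse strain carried by one set of donors could give such a pattern. The Fisher exact test (p = 0.00046) measures clustering and not strain, and sequence variants, which would test strain, were not analysed here.

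Near Csk itself, on chromosome 9, 4 of 50 neighbouring genes (8%) had an unadjusted p under 0.01 after the GC correction, against 2.35% elsewhere (one-sided Fisher exact p = 0.030).

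Csk was not lower in the libraries labelled Csk(f/f), with a log2 difference of 0.18, and gene-level values cannot decide whether deleted exons form a small part of the transcript. By the criterion set beforehand, an exchange of 1 library of each group was not argued against, since one such exchange gave 9 genes past the threshold where the labelled split gave 8. The Csk values argue against an exchange as the reason that Csk was not lower, since all 5 libraries lay between 378 and 476 FPKM and none was low. Counts looked at afterwards differed from that: of genes of at least 200 nt, 5 passed in the labelled split and at most 2 in any other. At an unadjusted p under 0.05 by limma, the labelled split gave 2221 genes, the exchanges at most 820, and splits of a pair of Csk(+/+) libraries against the rest up to 1459. These counts were made without the GC correction, after which the labelled split gave 1008. They therefore also follow the GC trend that the 2 libraries labelled Csk(f/f) share, and do not decide on an exchange. Exon-level values or genotyping would be needed to settle how far Csk was deleted in these cells.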
